A study of Mus musculus with 13 samples.

How the data were processed

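The series measured gene expression by RNA sequencing in the frontal cortex of wild-type B6SJLF1/J mice and of 5XFAD mice at 6 and 11 months of age. 5XFAD is a transgenic line that carries mutated human transgenes, among them APP, under the regulatory sequence of the mouse Thy1 gene and is used as a model of amyloid deposition. Total RNA was extracted with a column kit and made into Illumina libraries, per the labels' protocols. The 13 libraries fall into 4 groups: 4 wild-type and 3 5XFAD libraries at 6 months, and 3 wild-type and 3 5XFAD libraries at 11 months. Each library was placed in its group by its title, and replicates were numbered within a group in accession order, so equal numbers pair nothing. The titles carry a different number for each library, and nothing in the labels says whether the numbers are animals, so p-values measure the spread between these libraries, which may be partly technical.

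The authors aligned reads with STAR 2.7.1 and quantified genes with RSEM against GRCm38, per the submitters' processing notes. The RSEM version, the gene annotation and the strand setting are not given in the sources used here. The deposited files hold expected counts per gene, which RSEM estimates by sharing reads that fit several genes among them, and 7.24% to 7.71% of the values in a library were not whole numbers. The deposited TPM values, scaled for transcript length by the authors' quantifier, were used in 1 alternative only, and the FPKM column was not used. All 55536 gene identifiers matched the GENCODE M21 annotation of GRCm38, from which symbols and coordinates were taken. The human transgenes were not analysed here.

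Expected counts were rounded to whole numbers. Totals ran from 23618296 to 26615776 counts per library, and the mitochondrial share from 7.89% to 11.43%. No 2 libraries were alike beyond sampling noise: over the 78 pairs the smallest chi-square per gene was 6.49. Genes passed the filterByExpr rule of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17483 genes. Library totals were scaled by TMM. Then 1 negative binomial model with 4 group means was fitted over all 13 libraries, so that all comparisons share 1 estimate of the spread. The groups did not spread alike. Among wild-type libraries at 11 months the chi-square per gene was 53.59 to 60.85, against 10.44 to 19.81 among transgenic libraries of that age. At 6 months it was 6.49 to 33.68 in wild type and 9.17 to 19.55 in transgenic mice. The shared estimate may thus be too small for comparisons with wild type at 11 months and too large for others. The comparisons were tested with edgeR's robust quasi-likelihood test and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold, in R 4.3.3. Values after ± beside a log2 fold change are standard errors, computed as the absolute unshrunken log2 fold change divided by the square root of the quasi-likelihood F statistic. Levels are TMM-scaled CPM given as mean ± SD. Where a group was at 0 in all its libraries, a lower bound of the fold was computed against a floor of 3 counts over the group. Such floors cover counting error only.

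The design, the tests, 41 gene lists and the rule for named genes were fixed before the data were examined. The lists cover microglial states, complement, antigen presentation, interferon, innate receptors, phagocytosis, lysosome, astrocytes, the oligodendrocyte lineage, neurons and cortical layers, synapse, activity-dependent genes, metabolism, stress, Alzheimer risk loci, vessels and borders, blood cells, neighbouring brain regions, sex-linked genes and proliferation. Some genes stand in more than 1 list. Of the lists, 40 had at least 3 measured members and were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. Each test was repeated with a correlation estimated from the data, and counts of changed members are also given adjusted over the list alone. Named genes were App and Thy1; for each genotype comparison the 10 largest changes in each direction among genes past the threshold, with at least 1 CPM in the higher group and no overlap between the libraries; for the age comparisons and the interaction 5 in each direction, the interaction without the overlap condition; and the members of each list with the smallest p. Unnamed genes, pseudogenes, Xist, Tsix and Y-linked genes were skipped. To keep the text short, list members not past the threshold were left out first and then those with larger p within each list, which left 1 member per list in the genotype and age comparisons; applying the order within each list was decided after the values were seen. Some genes that the rule chose are not reported here, and none was named in their place. The marker Ttr was chosen after its values were seen. Genes with overlapping neighbours or close paralogs, among them Lilrb4a, Ccl3, Ccl4, Lyz2, C4b, Nrn1l and Lrrc24, are uncertain where reads were shared between copies.

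Alternatives were RLE scaling, library size scaling alone, DESeq2 1.42.0, limma voom, limma on log2(TPM + 1), 2 other filters on low counts, the compared groups alone, no robust spread, sex as a covariate, the number series in the titles as a covariate at 11 months, a minimum absolute log2 fold change of 1, and leaving out each library in turn. A covariate for striatal marker genes, an offset for transcript length and GC content, and a fit of male 6-month libraries alone were added after the data were seen. The trend with transcript length was computed per library as the slope of each gene's log2 CPM, relative to its mean over all libraries, on log2 transcript length. Sex was taken from Xist and Y-linked counts.

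The tests were tried on simulated counts drawn from the means, dispersions and library sizes of the 17483 genes. The 200 changed genes were taken from those averaging at least 1 CPM. Genes were simulated independently of each other, without trends shared within a library, so the shares of false calls need not hold for the real libraries. For a simulated comparison of 5XFAD against wild type at 6 months, edgeR recovered 46.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 92.4% of those changed 4-fold, with 3.9% false calls. For a simulated interaction of genotype and age the shares were 7.5%, 62.7% and 87.9%, with 6.2% false calls.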

Results

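Gene expression was measured in 13 libraries from the frontal cortex of mice of 2 genotypes and 2 ages. The wild-type groups held 4 libraries at 6 months and 3 at 11 months, and each 5XFAD group held 3. At 6 months the wild-type libraries held 23684382, 24461067, 25344893 and 24244226 counts and the 5XFAD libraries 25779948, 23956719 and 26216613. At 11 months the totals were 24045885, 25414945 and 23618296 in wild type and 24584476, 25407181 and 26615776 in 5XFAD. The sexes, read from Xist and Y-linked genes, were not balanced: all 3 5XFAD libraries at 6 months were male, while 2 of the 4 wild-type libraries of that age were female. At 11 months 2 of the 3 5XFAD libraries and 1 of the 3 wild-type libraries were female.

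Mouse genes related to the transgenes were examined first. Thy1 (ENSMUSG00000032011, GRCm38 chromosome 9, 44043384 to 44048579), whose regulatory sequence drives the transgenes, rose in 5XFAD from 725 ± 61.2 to 2772 ± 335 CPM at 6 months and from 577 ± 53.3 to 2820 ± 585 CPM at 11 months. The log2 fold changes were 1.93 ± 0.14 (adjusted p = 5.27e-06) and 2.29 ± 0.15 (adjusted p = 1.24e-06). Mouse App (chromosome 16, 84949685 to 85173766), the amyloid precursor protein gene, stood at 1325 ± 92.4 CPM in wild type and 1257 ± 82.6 CPM in 5XFAD at 6 months, with log2 fold changes of -0.08 ± 0.10 and 0.09 ± 0.11 at the 2 ages. App did not pass the test at either age. All 6 5XFAD libraries lay above every wild-type library for Thy1. Whether the added reads came from the mouse gene or from Thy1 sequence carried with the transgenes was not tested.

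The first comparison asked how the cortex of 5XFAD mice differs from wild type at 6 months. Genes of microglia, the resident macrophages of the brain, were higher in 5XFAD. Cst7, a cysteine protease inhibitor (chromosome 2, 150570415 to 150578944), rose from 0.1808 ± 0.138 CPM (n = 4) to 18.99 ± 2.05 CPM (n = 3), a log2 fold change of 6.67 ± 0.32. The integrin gene Itgax rose by 5.31 ± 0.33 on the log2 scale, Lilrb4a by 5.13 ± 0.39, the chemokine genes Ccl3 by 4.79 ± 0.42, Ccl4 by 3.80 ± 0.45 and Ccl6 by 3.15 ± 0.25, and the lysozyme gene Lyz2 by 3.14 ± 0.16. Milr1 (4.55 ± 0.54), the niacin receptor gene Hcar2 (4.21 ± 0.39) and the protease gene St14 (3.10 ± 0.24) completed the 10 largest increases. Milr1 held only 0.03879 to 0.1225 CPM in the wild-type libraries, so the size of its fold is uncertain. In edgeR's quasi-likelihood test 231 of 17483 genes changed, 228 of them higher in 5XFAD. The number of lower genes differed between methods: DESeq2 called 345 higher and 39 lower, and with log2(TPM + 1) values 137 were higher and 37 lower (78.7% higher, against 98.7% here). The 3 lower genes were Zkscan16 (-0.79 ± 0.17, adjusted p = 0.0404), Cacng8, a subunit gene of AMPA receptor complexes (-0.36 ± 0.08, adjusted p = 0.0447), and Lrrc24 (-0.35 ± 0.08, adjusted p = 0.0467).

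Of 27 measured disease-associated microglia genes, a set described in amyloid models, 20 rose at 6 months (24 adjusted over the list alone), with a median log2 fold change of 1.5. Homeostatic microglia genes rose in 7 of 15 cases (12 adjusted over the list alone; median 0.73), with Fcrls at 1.64 ± 0.17; the gene given for a list was chosen by its p, and other members can have larger folds. For that list the adjusted p was 0.0929 with an estimated correlation. Fc receptor and phagocytosis genes rose in 12 of 17 cases (14 adjusted over the list alone), with the Fc receptor chain gene Fcer1g at 1.73 ± 0.13. Lysosome genes rose in 18 of 33 cases (24 adjusted over the list alone), with the protease gene Ctsd at 344.6 ± 3.59 CPM in wild type and 864.6 ± 85.3 CPM in 5XFAD. Complement genes rose in 8 of 16 cases (9 adjusted over the list alone), with C1qa at 1.71 ± 0.14. Of MHC class II presentation genes 3 of 8 rose (4 adjusted over the list alone), among them the protease gene Ctss (1.69 ± 0.17). Toll-like receptor and NF-kB genes rose in 4 of 18 cases (7 adjusted over the list alone), with Tlr2 at 2.28 ± 0.22. Reactive astrocyte genes rose in 3 of 22 cases (8 higher and 1 lower adjusted over the list alone), with the protease inhibitor gene Serpina3n at 1.57 ± 0.15. Apart from the homeostatic list, camera called these lists with the preset and with the estimated correlation, the latter with adjusted p from 0.0117 to 0.0337. Leaving out any 1 of the 6-month libraries left 3 or 4 homeostatic microglia genes called, and 5 reactive astrocyte genes were called without wild-type replicate 3.

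Other lists were called at 6 months with the preset correlation only. MHC class I presentation genes rose in 4 of 15 cases (6 adjusted over the list alone), with B2m, the light chain of MHC class I, at 1.26 ± 0.16; the adjusted p was 0.156 with an estimated correlation. Type I interferon response genes rose in 3 of 27 cases (7 adjusted over the list alone), with Ifi27l2a at 2.42 ± 0.45; the adjusted p was 0.331 with an estimated correlation. Of 25 Alzheimer risk loci 6 rose (7 higher and 1 lower adjusted over the list alone), with the microglial receptor gene Trem2 at 2.17 ± 0.22; the adjusted p was 0.162 with an estimated correlation. Of 22 unfolded protein and heat shock genes 1 rose (2 adjusted over the list alone), the transcription factor gene Atf3 (1.62 ± 0.26), and the list had adjusted p = 0.548 with an estimated correlation. The transgene and promoter list was called through Thy1 alone (adjusted p = 0.0855 with an estimated correlation). Camera also placed cholesterol synthesis genes (median 0.29), mitochondrial genome genes (0.33), proliferation genes (0.71), oligodendrocyte and myelin genes (0.40), oligodendrocyte precursor genes (0.13) and astrocyte markers (0.15) higher. For these and the 5 lists named next the adjusted p lay between 0.255 and 0.671 with an estimated correlation. Camera placed cortical layer 6 (-0.29), endothelium (-0.25), mural cell (-0.17), meninges and fibroblast (-0.69) and striatum genes (-0.54) lower. No single member of these lists passed over all genes, while adjusted over the list alone 4 cholesterol synthesis, 4 mitochondrial genome and 1 proliferation gene were higher and 1 endothelium and 1 mural cell gene lower. The sex-linked list was called higher with a median of 0.95 and a mean of -0.71, opposite in sign, and with adjusted p = 0.331 with an estimated correlation. Females numbered 2 in wild type and 0 in 5XFAD at this age, so that list reflects the sexes of the libraries. Interferon genes called numbered 0 without wild-type replicate 4 or 5XFAD replicate 2 and 1 without wild-type replicates 1 or 2 or 5XFAD replicate 3. Risk loci called higher numbered 2 or 3 whichever library was left out. The preset calls by camera of astrocyte markers and oligodendrocyte precursors ended without wild-type replicates 2 or 4 or 5XFAD replicates 2 or 3 (adjusted p up to 0.184 and 0.215). Without wild-type replicate 3 the calls of endothelium (adjusted p = 0.125), mural cells (0.142), striatum (0.139) and the unfolded protein list (0.258) ended. Without 5XFAD replicate 3 those of endothelium (0.0852), striatum (0.822) and cortical layer 6 (0.281) ended, and without 5XFAD replicate 1 those of mural cells (0.0785) and the unfolded protein list (0.576). The sex-linked call ended without any library except 5XFAD replicate 1 (adjusted p up to 0.173).

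Camera did not call the remaining lists at 6 months. Their median log2 fold changes were 0.06 for excitatory neurons, -0.19 for inhibitory neurons, 0.09 for upper cortical layers, -0.05 for cortical layer 5, -0.03 for the synapse list, 0.02 for activity-dependent genes, 0.07 for the nuclear-encoded respiratory chain, -2.56 for choroid plexus, -0.01 for ependyma, 0.01 for red blood cells, -0.14 for border macrophages and monocytes, -0.16 for T and B lymphocytes, -0.01 for olfactory bulb, 0.02 for hippocampal dentate gyrus and -0.05 for thalamus. For upper cortical layers, activity-dependent genes, ependyma, red blood cells, olfactory bulb and thalamus the median, the mean and the direction of the test differed in sign. The choroid plexus score of wild-type replicate 1 at 6 months was 4.4 against -1.01 to 1.01 in the other 12 libraries. In that library Ttr, an abundant choroid plexus transcript chosen after its values were seen, reached 2912 CPM against 1.615 to 30.8 CPM elsewhere. Only 2 of the 10 neutrophil genes were measured, with a median of 0.27, and that list was not tested. The count of 231 genes became 170 without wild-type replicate 1, 141 without wild-type replicate 2, 151 without wild-type replicate 4, and 152, 152 and 143 without 5XFAD replicates 1, 2 and 3. DESeq2 called 384 in all. Per doubling of transcript length, log2 expression relative to the mean of all libraries changed by -0.097 to -0.062 in the 5XFAD libraries and by -0.048 to 0.002 in the wild-type libraries, with no overlap, and 215 genes were called with length and GC offsets. The calls of Zkscan16, Cacng8, Lrrc24 and Ifi27l2a ended without single libraries of either genotype (adjusted p up to 0.281 by edgeR), and male libraries alone gave 123 changed genes, 110 of them among the 231.

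**Figure D1:**
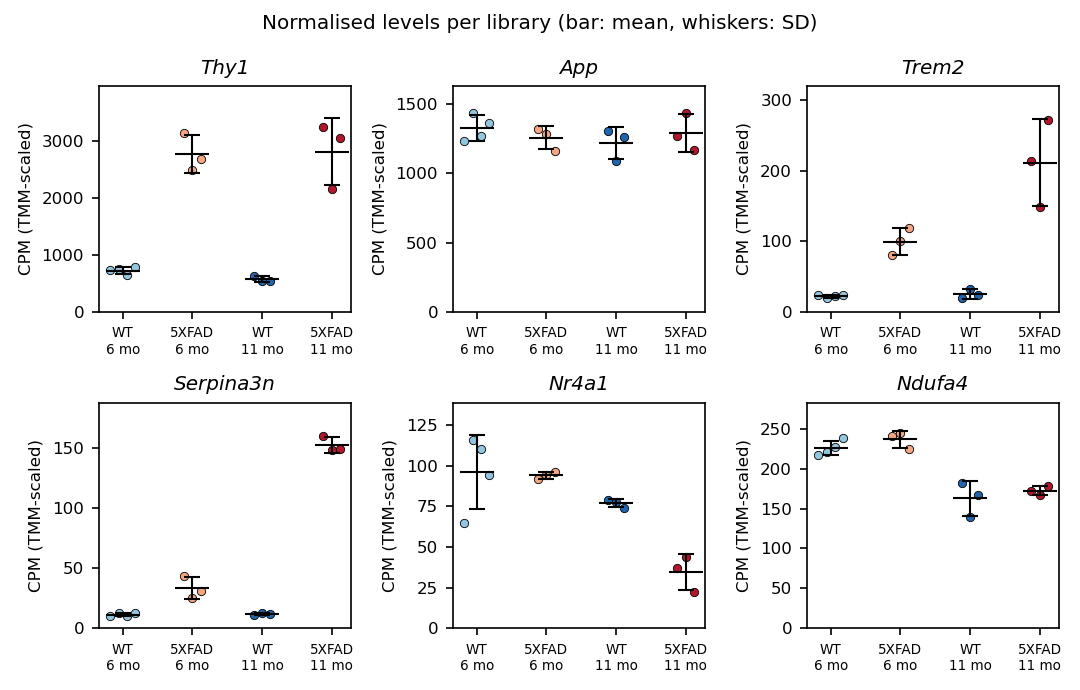
Levels of 6 genes in TMM-scaled CPM on linear axes from 0, 1 point per library, with bars at the group mean and whiskers of 1 SD (n = 4 for wild type at 6 months, n = 3 elsewhere). Thy1 averaged 725 and 2772 CPM in the 6-month groups, App did not pass the test, and Serpina3n averaged 152.3 CPM in 5XFAD at 11 months.

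The same genotype comparison was made at 11 months. Cst7 rose from 0.2843 ± 0.107 to 61.32 ± 12.1 CPM (n = 3 each), a log2 fold change of 7.73 ± 0.34, and Itgax (6.54 ± 0.35), Lilrb4a (6.36 ± 0.42) and Ccl3 (5.44 ± 0.45) again stood among the 10 largest increases. The others were the protease gene Ctse (6.86 ± 0.69), the immune checkpoint receptor gene Pdcd1 (6.35 ± 0.64), the cytokine gene Tnfsf8 (5.99 ± 0.80), Asb10 (4.99 ± 0.45), the interferon-induced gene Ifi207 (4.95 ± 0.71) and Atp6v0d2, a proton pump subunit gene. Atp6v0d2 had no counts in wild type at 11 months and 1.64 CPM in 5XFAD, at least 40.3-fold higher against a floor of 3 counts over the group. Ctse averaged 0.0139 CPM in the same wild-type group, under that floor of 0.0406 CPM, so the size of its fold is uncertain. In total 753 genes changed, 665 higher and 88 lower in 5XFAD. With log2(TPM + 1) values 518 were higher and 338 lower (60.5% higher, against 88.3% here), on a scale where the median log2 fold change of all genes was -0.118 at 11 months and -0.107 at 6 months. DESeq2 called 908 higher and 220 lower, and with sex as a covariate 636 genes were called, 618 of them among the 753. Per doubling of transcript length, log2 expression changed by 0.004 to 0.041 in the 5XFAD libraries and by 0.037 to 0.138 in wild type. With length and GC offsets 702 genes were called, 624 of them among the 753.

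Nr4a1 (chromosome 15, 101254269 to 101274795), an activity-induced nuclear receptor gene, fell at 11 months from 77.07 ± 2.59 to 34.63 ± 10.9 CPM (-1.15 ± 0.23, adjusted p = 0.00993), and the activity-induced transcription factor gene Egr4 changed by -1.13 ± 0.28 (adjusted p = 0.0395). The interneuron peptide gene Cort (-1.73 ± 0.46), Nrn1l (-1.65 ± 0.41), Rpe65 (-1.37 ± 0.35), the calcium release channel gene Ryr1 (-1.24 ± 0.24), the orexin receptor gene Hcrtr1 (-1.24 ± 0.31), the serotonin receptor gene Htr7 (-1.13 ± 0.29), Gpr3 (-1.12 ± 0.25) and Kirrel2 (-1.12 ± 0.22) were the other 8 of the 10 largest decreases. Of 24 activity-dependent genes 4 fell over all genes and 21 adjusted over the list alone, with a median of -0.92. Camera called this list at adjusted p = 5.71e-13, and the value was adjusted p = 0.0713 with an estimated correlation. Inhibitory neuron genes were placed lower with 1 of 18 called, Cort (1 adjusted over the list alone), and the call of Cort (adjusted p = 0.0499 by edgeR) ended with RLE scaling. For that list the adjusted p was 0.301 with an estimated correlation, and the preset call ended without wild-type replicates 1 or 3 or 5XFAD replicate 3 (up to 0.108). Activity-dependent genes called numbered 2 without wild-type replicate 3 or 5XFAD replicate 1, 7 without 5XFAD replicate 2 and 1 without 5XFAD replicate 3. Inhibitory neuron genes called numbered 0 without wild-type replicate 1 or 5XFAD replicates 1 or 3 and 2 without wild-type replicate 2.

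Genes of microglia and of immune functions rose at 11 months as well. Disease-associated microglia genes rose in 25 of 27 cases (27 adjusted over the list alone; median 2.99) and homeostatic microglia genes in 12 of 15 (14 adjusted over the list alone; median 1.11); for the homeostatic list the adjusted p was 0.0688 with an estimated correlation. Lysosome genes rose in 27 of 33 cases (30 adjusted over the list alone), with Ctsd at 2.10 ± 0.12. Complement genes rose in 10 of 16 cases (12 adjusted over the list alone), with C1qa at 2.23 ± 0.16, and Fc receptor and phagocytosis genes in 15 of 17 (16 adjusted over the list alone), with Fcer1g at 2.31 ± 0.14. MHC class II presentation genes rose in 6 of 8 cases (7 adjusted over the list alone), with the invariant chain gene Cd74 at 3.51 ± 0.30, and toll-like receptor and NF-kB genes in 6 of 18 (15 adjusted over the list alone), with Tlr2 at 2.68 ± 0.24. Reactive astrocyte genes rose in 15 of 22 cases (17 adjusted over the list alone), with Serpina3n (chromosome 12, 104406729 to 104414329) at 11.66 ± 0.808 CPM in wild type and 152.3 ± 6.64 CPM in 5XFAD (3.71 ± 0.18). Apart from the homeostatic list, camera called these lists under both correlations, with adjusted p from 0.00588 to 0.00806 for the estimated one. Without wild-type replicate 2 there were 10 toll-like receptor and NF-kB genes called.

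Type I interferon response genes rose in 20 of 27 cases at 11 months (26 adjusted over the list alone), with the chemokine gene Cxcl10 at 4.42 ± 0.58; the adjusted p was 0.0713 with an estimated correlation. MHC class I presentation genes rose in 11 of 15 cases (13 adjusted over the list alone), with B2m at 1.90 ± 0.17; the adjusted p was 0.065 with an estimated correlation. Of the Alzheimer risk loci 9 of 25 rose (11 adjusted over the list alone), with Trem2 at 3.06 ± 0.25, and the adjusted p was 0.0831 with an estimated correlation. Cholesterol synthesis genes rose in 4 of 20 cases (7 adjusted over the list alone), and the adjusted p was 0.542 with an estimated correlation. Of the unfolded protein and heat shock genes 2 of 22 rose (2 adjusted over the list alone), with Atf3 at 2.79 ± 0.29. That list, the mitochondrial genome (median 0.14), endothelium (-0.27) and proliferation (0.45) were called with the preset correlation only, with adjusted p from 0.705 to 0.781 with an estimated correlation. The transgene and promoter list was again called through Thy1 alone (adjusted p = 0.0688 with an estimated correlation). Outside the called lists, the water channel gene Aqp4 of astrocytes rose by 0.98 ± 0.18, the monocyte receptor gene Ccr2 by 2.53 ± 0.67, the lymphocyte gene Cd5 by 3.11 ± 0.66 and the layer 4 gene Rorb by 0.68 ± 0.17. Interferon genes called numbered 13 without wild-type replicate 3 and 12 without 5XFAD replicate 3, and unfolded protein genes 1 without the latter. Cholesterol synthesis genes called numbered 0 without wild-type replicate 3 or 5XFAD replicate 1, 1 without wild-type replicate 2 and 2 without 5XFAD replicate 3. The preset call by camera of the mitochondrial genome ended without wild-type replicate 1 (adjusted p = 0.837) or 5XFAD replicates 2 (0.0553) or 3 (0.0661), and that of endothelium without wild-type replicate 2 (0.645) or 5XFAD replicate 1 (0.0546). That of the unfolded protein list ended without wild-type replicate 2 (0.463) or 5XFAD replicates 2 (0.0781) or 3 (0.105), and that of proliferation without wild-type replicates 2 (0.242) or 3 (0.216) or 5XFAD replicates 1 (0.0521) or 2 (0.338). There was 1 called mitochondrial genome gene without wild-type replicate 2, and 1 each for endothelium and proliferation without wild-type replicate 1. The count of 753 became 463 without 5XFAD replicate 3 and 424 with the 11-month groups alone. Without that replicate 9 of the 10 named genes that fell lost their call, Nr4a1 keeping it, and Rorb, Ccr2 and Cd5 lost theirs without at least 1 library (adjusted p up to 0.241 by edgeR).

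**Figure D2:**
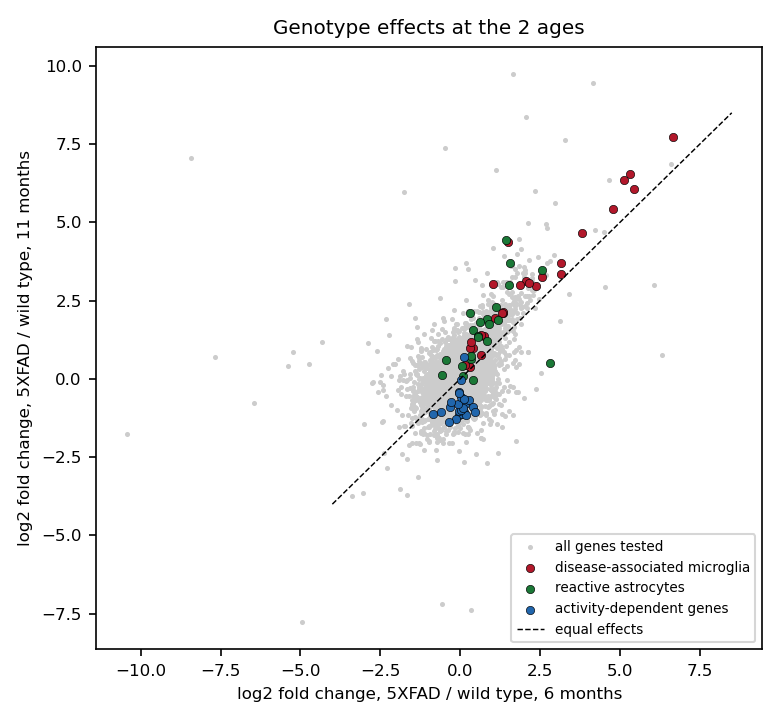
Log2 fold changes of 5XFAD over wild type at 6 months (horizontal) and 11 months (vertical) for 17483 genes in grey, with 3 gene lists in colour and a dashed line of equal effects. Disease-associated microglia genes had medians of 1.5 and 2.99, and activity-dependent genes of 0.02 and -0.92; grey points far from the centre include genes with few counts.

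The genotype effects at the 2 ages were compared with each other, and these comparisons share no library. Of the 228 genes higher in 5XFAD at 6 months, 218 were also called higher at 11 months, where 8.7 would be shared by independent lists, and 206 had the larger log2 fold change at 11 months. Across all genes the log2 fold changes had a Pearson r of 0.541 and a Spearman rho of 0.458, a description across genes, which are not independent replicates. None of the 3 genes lower at 6 months was called at 11 months. The difference between the ages was tested as the interaction of genotype and age, and 1 gene passed: for Serpina3n the genotype effect was larger by 2.13 ± 0.23 at 11 months (adjusted p = 0.00456). At an unadjusted p under 0.05 there were 692 of 17483 genes, a share below the 0.05 that chance alone gives, and DESeq2 called 30. The interaction values of App (0.16 ± 0.14) and Thy1 (0.35 ± 0.20) did not pass. Camera called 18 of 40 lists for the interaction, and 1 of them, reactive astrocytes (median 0.82), with an estimated correlation at adjusted p = 0.0204.

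The third comparison asked what differed between 11 and 6 months in wild type. The named genes with the largest differences were Pagr1a (3.10 ± 0.70), the long noncoding RNA gene Fendrr (1.82 ± 0.45), Zbed6 (1.68 ± 0.25), Igsf6 (1.43 ± 0.27) and the hypoxia factor gene Hif3a (1.33 ± 0.26), which rose, and Plb1 (-1.23 ± 0.29), the surfactant protein gene Sftpc (-1.15 ± 0.30), Tmsb15b1 (-1.10 ± 0.28), the muscle phosphoglycerate mutase gene Pgam2 (-1.05 ± 0.24) and Aldh1b1 (-0.96 ± 0.23), which fell. Pagr1a, Zbed6 and Tmsb15b1 overlap other tested genes on the same strand, so their counts depend on how RSEM shared the reads. In total 649 genes changed, 423 higher and 226 lower at 11 months, with a median absolute log2 fold change of 0.48. With library size scaling alone 79.9% of the changed genes were higher, and with log2(TPM + 1) values 89.9%, against 65.2% here. The count depended on single libraries: by edgeR it was 0 without 6-month replicate 4, 47 without replicate 2, and 133 and 424 without replicates 1 and 3 of that age, 2 and 1949 without 11-month replicates 2 and 1, and 1 with the wild-type groups fitted alone. It was 68 with length and GC offsets, 175 with the striatum score, 345 with sex and 1430 with the number series as a covariate, and 296 with log2(TPM + 1) values. All 22 named genes called here lost the call without at least 1 library, DESeq2 called 1843 genes with all libraries, and 4156 had an unadjusted p under 0.05.

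Camera called 17 lists with age in wild type, 12 higher and 5 lower, with the preset correlation only. For all 17 lists the call was lost, with adjusted p from 0.281 to 0.651 with an estimated correlation. Endothelium genes rose in 8 of 14 cases (12 adjusted over the list alone), with the VEGF receptor gene Flt1 at 1.02 ± 0.19, and astrocyte markers in 6 of 14 (12 adjusted over the list alone), with the connexin gene Gjb6 at 0.94 ± 0.16. Of oligodendrocyte precursor genes 3 of 12 rose (4 adjusted over the list alone), with Cspg4 at 0.63 ± 0.14; of border macrophage and monocyte genes 2 of 7 (4 adjusted over the list alone), with Stab1 at 1.06 ± 0.19; and of mural cell genes 1 of 12 (7 adjusted over the list alone), Notch3 at 0.86 ± 0.21. Complement genes rose in 1 of 16 cases (8 adjusted over the list alone), phagocytosis genes in 1 of 17 (3 adjusted over the list alone), Mertk at 0.96 ± 0.19, and risk loci in 2 of 25 (3 adjusted over the list alone), with Cd33 at 0.96 ± 0.19. Homeostatic microglia genes (median 0.50), MHC class I presentation (0.22), the mitochondrial genome (0.20) and red blood cells (0.83) were placed higher with no member called over all genes and 12, 0, 1 and 1 adjusted over the list alone. Nuclear-encoded respiratory chain genes fell in 9 of 30 cases (27 adjusted over the list alone; median -0.32), with Ndufa4 (chromosome 6, 11900292 to 11907497) at 225.5 ± 9.08 CPM at 6 months and 162.6 ± 21.9 CPM at 11 months. The change of log2 expression per doubling of transcript length was 0.037 to 0.138 in the wild-type libraries at 11 months against -0.048 to 0.002 at 6 months, and with length and GC offsets 0 of the 30 nuclear-encoded respiratory chain genes were called. Cortical layer 6 (-0.63; 3 adjusted over the list alone), ependyma (-0.55), T and B lymphocytes (-0.83) and striatum (-0.71) were placed lower with no member called over all genes. The striatum scores of the wild-type libraries were 6.48, 5.81, 6.9 and 5.57 at 6 months and 4.38, 2.9 and 6.88 at 11 months. Without 6-month replicates 2 or 4 or 11-month replicate 2 none of these 17 lists kept a called member, and nuclear-encoded respiratory chain genes called numbered 1 without 6-month replicates 1 or 3, 3 without 11-month replicate 3 and 23 without 11-month replicate 1. Without 6-month replicate 1 the called members numbered 0 for endothelium, oligodendrocyte precursors, mural cells, phagocytosis and risk loci and 1 for astrocyte markers and border macrophages. Without 6-month replicate 3 there was 1 called oligodendrocyte precursor gene and 1 border macrophage gene, and without 11-month replicate 3 there were 1 oligodendrocyte precursor and 3 mural cell genes. Lists with no called member had 1 for homeostatic microglia and cortical layer 6 without 6-month replicate 3, and for MHC class I presentation, cortical layer 6 and striatum without 11-month replicate 3. Without 11-month replicate 1 the numbers were 10 for astrocyte markers and for homeostatic microglia, 8 for complement and for the mitochondrial genome, 6 for risk loci, 5 for phagocytosis, 4 for cortical layer 6, 3 for mural cells and 2 for ependyma. Outside the called lists, Lyz2 (1.08 ± 0.17), Srgn (0.61 ± 0.13), Glis3 (0.87 ± 0.22) and the synaptic scaffold gene Shank2 (0.88 ± 0.15) rose, while App (-0.12 ± 0.10) and Thy1 (-0.33 ± 0.14) did not pass.

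The fourth comparison set 11 against 6 months in 5XFAD. Gpnmb, a glycoprotein gene of the disease-associated microglia list, rose from 5.036 ± 2.11 to 41.1 ± 11.2 CPM (3.03 ± 0.35, n = 3 each), ahead of Adnp (2.98 ± 0.77), the glucuronosyltransferase gene Ugt1a7c (2.95 ± 0.57), Atp6v0d2 (2.59 ± 0.64) and Slc22a18 (2.40 ± 0.41). The 5 largest decreases were in the activity-induced genes Egr2 (-2.39 ± 0.39), Fos (-1.81 ± 0.34), Arc (-1.81 ± 0.34) and Egr4 (-1.58 ± 0.28) and in Arl4d (-1.64 ± 0.28). Adnp and Ugt1a7c overlap other tested genes on the same strand. In total 1264 genes changed, 847 higher and 417 lower at 11 months; 77.6% were higher with library size scaling alone and 89.6% with log2(TPM + 1) values, against 67% here.

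Activity-dependent genes fell in 11 of 24 cases in this comparison (17 adjusted over the list alone; median -0.97), with Nr4a1 at -1.44 ± 0.23, and the adjusted p was 0.0871 with an estimated correlation. Respiratory chain genes fell in 14 of 30 cases (24 adjusted over the list alone; median -0.35), with Cox5a at -0.59 ± 0.10 and adjusted p = 0.123 with an estimated correlation. The change of log2 expression per doubling of transcript length was 0.004 to 0.041 in the 5XFAD libraries at 11 months against -0.097 to -0.062 at 6 months, and with length and GC offsets 6 of the nuclear-encoded respiratory chain genes were called. Reactive astrocyte genes rose in 11 of 22 cases (17 adjusted over the list alone), with Serpina3n at 2.19 ± 0.16, the 1 list called under both correlations (adjusted p = 0.048 for the estimated one). Disease-associated microglia genes rose in 19 of 27 cases (23 adjusted over the list alone), lysosome genes in 26 of 33 (28), complement genes in 10 of 16 (13), Fc receptor and phagocytosis genes in 11 of 17 (15), MHC class II presentation genes in 6 of 8 (6) and toll-like receptor and NF-kB genes in 7 of 18 (9), each with the count adjusted over the list alone in parentheses and with adjusted p = 0.0611 with an estimated correlation. Without 11-month replicate 3 the called members numbered 5 for activity-dependent genes, 0 for the nuclear-encoded respiratory chain, 10 for disease-associated microglia, 12 for lysosome and 0 for toll-like receptor and NF-kB genes. Without 6-month replicates 1 and 2 they numbered 5 and 7, 1 and 1, 11 and 12, 17 and 16, and 2 and 1 in that order. Respiratory chain genes called numbered 5, 3 and 2 without 6-month replicate 3 and 11-month replicates 1 and 2, and toll-like receptor and NF-kB genes 2, 3 and 4. Without 6-month replicate 3 there were 7 activity-dependent genes. Fc receptor and phagocytosis genes numbered 4, 5 and 6 without 6-month replicates 1, 2 and 3 and 2 without 11-month replicate 3. MHC class II presentation genes numbered 3 without 6-month replicate 1 and 2 without 11-month replicate 3, and reactive astrocyte and complement genes 7 and 6 without 6-month replicate 2 or 11-month replicate 3. Examples were Hexa (0.79 ± 0.10), C4b (1.80 ± 0.24), Cd74 (1.88 ± 0.27) and Tlr7 (1.36 ± 0.25).

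Camera called 15 further lists in 5XFAD with age under the preset correlation only, and their adjusted p lay from 0.078 to 0.706 with an estimated correlation. Homeostatic microglia genes rose in 11 of 15 cases, MHC class I presentation genes in 10 of 15 (Tap1 1.28 ± 0.21), interferon genes in 7 of 27 (Trim30a 1.24 ± 0.25) and risk loci in 10 of 25 (Plcg2 1.16 ± 0.18). Adjusted over the list alone these counts were 15, 13, 20 and 10. Endothelium genes rose in 7 of 14 cases (Cdh5 1.32 ± 0.18), astrocyte markers in 3 of 14 (Aqp4 0.87 ± 0.18), mural cell genes in 3 of 12 (Notch3 1.23 ± 0.23) and meninges and fibroblast genes in 3 of 13 (Col3a1 2.21 ± 0.57). Adjusted over the list alone these were 10, 11, 6 and 7. Border macrophage and monocyte genes rose in 3 of 7 cases (Mrc1 1.91 ± 0.49) and oligodendrocyte precursor genes in 1 of 12 (Cspg4 0.67 ± 0.15), with 6 and 2 adjusted over the list alone. Red blood cell genes (0.78) were placed higher, and oligodendrocyte and myelin (-0.35), inhibitory neuron (-0.22), striatum (-1.31) and proliferation genes (-0.47) lower, with no called member by either adjustment. The striatum scores of the 5XFAD libraries were 6.08, 6.22 and 4.37 at 6 months and 4.72, 4.91 and 3.23 at 11 months. Without 11-month replicate 3 the called members numbered 4 for homeostatic microglia, 2 for MHC class I presentation, 4 for risk loci, 1 for endothelium and for mural cells, and 0 for interferon, astrocyte markers, meninges and fibroblasts, border macrophages and oligodendrocyte precursors. Without 6-month replicate 1 they numbered 4, 3, 6, 1 and 1 in that order and 0 for the same last 5 lists. Without 6-month replicate 2 homeostatic genes numbered 5, risk loci 6, interferon genes 2, endothelium and mural cell genes 1 each, and the last 4 lists 0. Without 6-month replicate 3 there was 1 called gene each for interferon, astrocyte markers, endothelium, mural cells, meninges and border macrophages. Interferon genes numbered 2 and 12 without 11-month replicates 1 and 2, endothelium and mural cell genes 2 and 1 without replicate 2, and meninges and border macrophage genes 0 and 1 without replicate 1. Shank2 (0.77 ± 0.16), Glis3 (1.20 ± 0.24) and Lef1 (1.17 ± 0.23) rose outside the called lists and Atf4 changed by -0.39 ± 0.08, and App (0.04 ± 0.11) and Thy1 (0.02 ± 0.15) did not pass. The count of 1264 became 236, 308 and 572 without 6-month replicates 1, 2 and 3, 608, 805 and 148 without 11-month replicates 1, 2 and 3, and 2579 with the 5XFAD groups alone. DESeq2 called 2063 genes, and 825 were called with log2(TPM + 1) values and 651 with the striatum score as a covariate. With sex as a covariate 883 genes were called, 717 of them among the 1264. Of the 30 named genes called here 18 lost the call without at least 1 of these libraries (adjusted p up to 0.16 by edgeR). With log2(TPM + 1) values the calls of Notch3, Col3a1, Mrc1, Tlr7 and Atf4 ended. Between the genotypes, 196 genes were called higher with age in both, where independent lists would share 20.5, and 111 lower, where they would share 5.4. The trend with transcript length also separated the ages in both genotypes. A library or dissection batch that follows age would be shared by the genotypes too, so this overlap does not set age apart from such a batch.

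**Figure D3:**
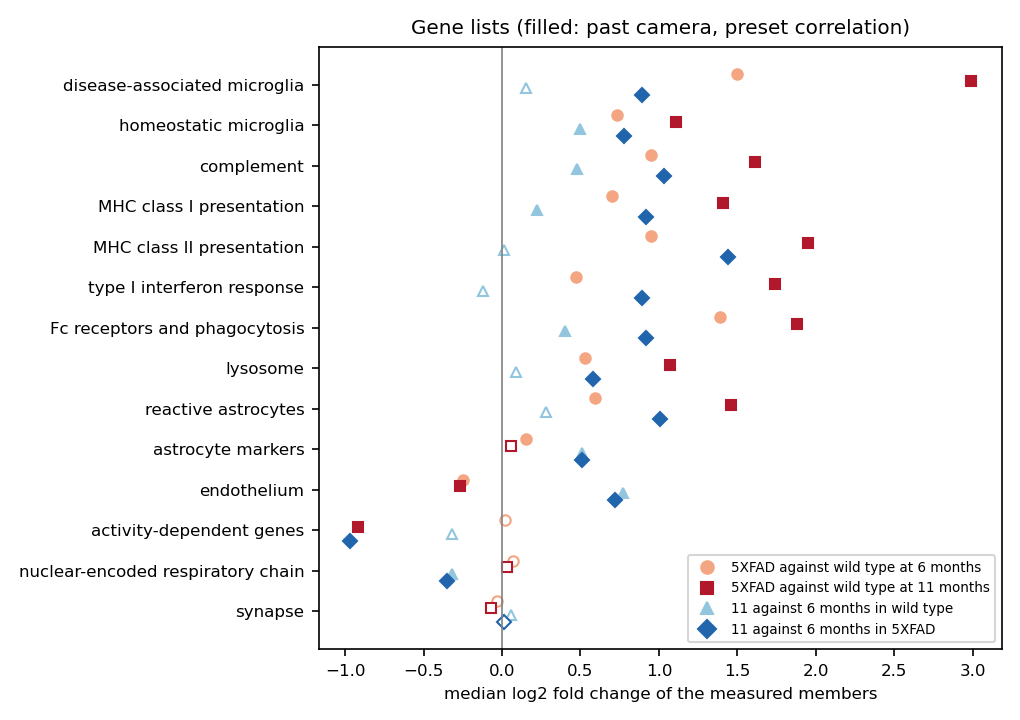
Median log2 fold change of the measured members of 14 gene lists (horizontal) in the 4 pairwise comparisons, filled where camera with the preset correlation called the list. Activity-dependent genes lay at -0.92 in the 11-month genotype comparison and -0.97 with age in 5XFAD, and respiratory chain genes at -0.32 and -0.35 with age in wild type and 5XFAD.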

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

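The tests of microglia number, of border macrophages, of monocytes, of list scores by sex and of the length trend per library were chosen after the results they bear on had been seen, and the striatum covariate, the length and GC offsets and the fit of male libraries were added after the data were seen. The genotype effect on Serpina3n differed between the ages by 2.13 in the interaction test. The gene lists whose genotype effect differed between the ages in camera with the preset correlation had median interaction values of 0.77 for disease-associated microglia, 0.33 for homeostatic microglia, 0.38 for complement, 0.63 for MHC class I presentation, 1.06 for MHC class II presentation, 1.05 for type I interferon response, 0.43 for toll-like receptor and NF-kB genes, 0.48 for Fc receptors and phagocytosis, 0.47 for lysosome, 0.82 for reactive astrocytes, -0.25 for oligodendrocytes and myelin, 0.24 for cortical layer 6, -0.95 for activity-dependent genes, -0.13 for the mitochondrial genome, 0.12 for Alzheimer risk loci, 0.62 for meninges and fibroblasts, 0.49 for T and B lymphocytes and -2.19 for sex-linked genes. With an estimated correlation 1 of these 18 calls held, that of reactive astrocytes.

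Among the 4 wild-type libraries at 6 months, 9 of 130 measures had 1 library far from the other 3, where chance gives about 6.5. The rule needs 4 values, so the groups of 3 libraries were not checked and the count says nothing about them. Replicate 1 had a choroid plexus score of 4.4 (mean log2 CPM) against 0.05 to 0.37, and stood apart for Pdcd1 (0 CPM), Rpe65 (3.194 CPM) and Atf4 (133.8 CPM). Replicate 2 stood apart for Trem2 (19.26 CPM), Sftpc (1.097 CPM) and Plcg2 (3.129 CPM), and replicate 4 for Milr1 (0.1225 CPM) and the cortical layer 6 score (4.93 against 5.27 to 5.30). The other libraries held 0.03879 to 0.04085 CPM for Pdcd1 and 0.03879 to 0.04095 CPM for Milr1, so both measures rest on very few reads.

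Disease-associated microglia genes were higher in 5XFAD than homeostatic microglia genes. The difference between the 2 scores per library was larger in 5XFAD by 1.41 ± 0.06 at 6 months and by 1.91 ± 0.21 at 11 months. This restates the pattern with its spread between libraries and is not a separate test. More microglia of an unchanged state would raise both lists alike, so the pattern itself argues against that as the whole cause. The monocyte gene Ccr2 was taken out of the border macrophage and monocyte list after its value was seen. The 6 other measured members had medians of -0.17 at 6 months (0.74 for 2 standard errors over members) and -0.19 at 11 months. These lay below the disease-associated list by 1.68 and 3.18 (2 standard errors of these differences over members, 1.16 and 0.99). Scores of the whole border list were low, from -1.21 to 0.5 (mean log2 CPM). The medians argue against border macrophages as the whole cause only as far as these few weakly expressed genes mark them. In male 6-month libraries alone the disease-associated list kept a median of 1.53 (0.96 for 2 standard errors over members), and its scores were 5.01 to 5.33 in 5XFAD against 2.98 to 3.07 in male and 2.92 to 3.12 in female wild type, which argues against sex as the cause at 6 months. Monocytes stay open, since Ccr2 alone speaks for them, at 0.88 ± 0.72 at 6 months and 2.53 ± 0.67 at 11 months, beside genotype, with which a change of microglial state is a hypothesis.

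Activity-dependent genes were lower in 5XFAD at 11 months. With the striatum score as a covariate the list median was -0.86 and with sex as a covariate -0.93. Both lay under the bound of -0.5, so neither covariate took the shift of the median away. The 2 standard errors over members (0.22 each) treat genes that respond together as independent and do not measure the spread between libraries. These medians therefore do not exclude striatal tissue or sex. The striatum scores of the libraries ran from 2.9 to 6.9. Time of day, handling before death and the interval to dissection, to which these genes respond within minutes, were not recorded in the labels and stay open beside genotype. Without each 11-month library in turn the list median lay between -1.09 and -0.78.

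Nuclear-encoded respiratory chain genes were lower at 11 than at 6 months in both genotypes. Long transcripts were higher and short ones lower at 11 months, and random lists matched on length, GC content and expression had medians of -0.21 in wild type and -0.22 in 5XFAD, so the trend covers much of the list's -0.32 and -0.35. The list lay at percentiles 0.02 and 0.04 of 10000 such lists, so it fell further than matched genes did in these libraries. With length and GC offsets its medians were -0.12 and -0.18, with 0 called members in wild type and 6 in 5XFAD. The random lists hold unrelated genes, so the percentiles do not measure the spread between libraries. Camera with an estimated correlation called the list in neither genotype, so chance stays open for what the trend does not cover. Leaving out the wild-type library with choroid plexus RNA gave -0.33, which argues against that library as the cause. The slope of expression on transcript length did not overlap between the ages in 2 of 2 genotypes, as a library or dissection batch that follows age would give. Such a batch and age cannot be told apart here. The slope also separated the genotypes at 6 months (-0.097 to -0.062 in 5XFAD, -0.048 to 0.002 in wild type), where the title numbers split by genotype too. At 11 months it was lower in 5XFAD with a narrow overlap (0.004 to 0.041, against 0.037 to 0.138 in wild type).

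Other divisions of the libraries into groups of the same sizes were fitted on the compared groups alone. At 6 months the real genotype split gave 265 changed genes and the highest of the other splits 28. With 1 of 35 as large, the smallest share that 35 splits can give, the values argue against chance but do not exclude it. Every other split placed libraries of both genotypes in at least 1 group, so these splits do not show counts without a genotype effect. At 11 months the real split gave 424 and the highest other 5, and for age in 5XFAD 2579 and 0; in both, 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05. For age in wild type the real split gave 1 changed gene, with 5 of 35 as large, the real one included, so chance is not excluded, and the highest other split, 6 genes, set the 3 female libraries against the 4 male ones. For the interaction the real labels gave 1 gene, and 14 of 100 labellings of genotype within age, the real one included, gave as many or more. Relabelled groups still hold genotype effects, so these labellings do not show what chance alone gives, and chance stays open for that count. The highest other gave 780; it exchanged most genotype labels at 6 months and kept those at 11 months, so that it adds the genotype effects of the 2 ages in place of subtracting them.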

How the results depend on the processing

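Of 113 calls of named genes, 56 held with RLE scaling, DESeq2, log2(TPM + 1) and each library left out, and none changed direction under these settings. RLE scaling alone kept 111, DESeq2 108 and log2(TPM + 1) 98. Leaving out 1 library ended between 4 (5XFAD replicate 2 at 11 months) and 28 calls (5XFAD replicate 3 at 11 months). The cause was not tested except where fewer libraries or a stricter rule made it plain.

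Genotype at 6 months gave 231 changed genes, 384 with DESeq2, 123 in male libraries alone (5 libraries) and 141 to 205 when 1 library was left out; other settings stayed within 1.5 times. Genotype at 11 months gave 753, then 424 with the compared groups alone, 440 with a minimum fold and 463 to 871 when 1 library was left out. Age in wild type gave 649, then 1843 with DESeq2, 296 with log2(TPM + 1), 1 with the compared groups alone, 345 with sex, 1430 with the number series, 175 with the striatum score, 68 with length and GC offsets, 59 with a minimum fold and 0 to 1949 when 1 library was left out. Age in 5XFAD gave 1264, then 2063 with DESeq2, 825 with log2(TPM + 1), 2579 with the compared groups alone, 651 with the striatum score, 328 with a minimum fold and 148 to 805 when 1 library was left out. The interaction gave 1, then 30 with DESeq2, 4 with log2(TPM + 1), 2 with the number series and 1 to 3 when 1 library was left out. The male fit, the striatum score and the offsets were chosen after seeing the data. With the compared groups alone, counts fell in the comparisons that hold wild type at 11 months, the group with the widest spread. They rose for genotype at 6 months (265) and for age in 5XFAD. These fits also hold fewer libraries, and the part due to the unequal spread was not separated.

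On the log2(TPM + 1) scale the median over all genes was -0.107 and -0.118 in the genotype comparisons, and 78.7% and 60.5% of changed genes were higher, against 98.7% and 88.3%. Of the gene lists called, 25, 19, 17, 24 and 18 in the 5 comparisons in the order above, an estimated correlation kept 7, 7, 0, 1 and 1, and fry called 11, 14, 8, 19 and 2. Leaving out 1 library gave 21 to 24 lists at 6 months and 16 to 23 at 11 months; list tests of age and of the interaction were not repeated in this way. The correlation of genotype effects, 0.541, was 0.67 for genes of at least 1 CPM and 0.606 on the log2(TPM + 1) scale. It was 0.498 without the microglia, complement, MHC and interferon lists, with the other immune lists kept. When 1 library was left out it was 0.409 to 0.539. At these depths the simulated interaction recovered 7.5% of 1.5-fold changes, so small differences between the ages were mostly not detectable.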

Other observations

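The 8 gene families below, and their values with length and GC offsets, were chosen after the results were seen. Their p-values were adjusted over these 8 families only and do not allow for that choice. Cathepsin, chemokine and toll-like receptor genes also stand in lists called above, so these families are not separate support. Cathepsin genes, a family of proteases, rose in 5XFAD in 9 of 13 cases at 6 months (median 0.64) and in 10 of 13 at 11 months (median 1.43), and camera called the family with an estimated correlation at adjusted p = 0.00572 and 0.004; the medians were 0.35 and 1.14 on the log2(TPM + 1) scale, with 5 and 9 called. Chemokine genes of the Ccl and Cxcl families rose in 5 of 17 cases at 6 months and 6 of 17 at 11 months, with adjusted p = 0.00572 and 0.00487 with an estimated correlation, and their medians of 0.68 and 0.84 were 0.34 and 0.95 on the log2(TPM + 1) scale. Cytosolic ribosomal protein genes rose in 10 of 74 cases at 6 months (median 0.25) and in 26 of 74 at 11 months (median 0.30), with adjusted p = 0.029 and 0.0547 with an estimated correlation; the medians were 0.12 and 0.18 on the log2(TPM + 1) scale, with 0 and 2 called. With length and GC offsets the ribosomal medians were 0.14 and 0.15, with 1 and 2 called, and with library size scaling alone 1 and 9 were called. The 5XFAD libraries at 6 months had steeper negative slopes on transcript length (-0.097 to -0.062) than the wild-type libraries (-0.048 to 0.002). At 11 months the slopes were 0.004 to 0.041 in 5XFAD and 0.037 to 0.138 in wild type, again lower in 5XFAD with a narrow overlap. Toll-like receptor genes rose in 3 and 4 of 10 cases at the 2 ages, with adjusted p = 0.0846 and 0.0449 with an estimated correlation, and their medians of 0.80 and 1.39 were 0.33 and 0.36 on the log2(TPM + 1) scale, with 1 and 4 called. The medians of these 4 families stayed above 0 under the scalings tried and with the offsets. Camera placed collagen genes lower in 5XFAD at 6 months (median -0.39), a call lost at adjusted p = 0.2 with an estimated correlation; at 11 months the median was -0.02 (adjusted p = 0.927 with an estimated correlation), and by edgeR 0 of 43 were called at either age. Of V-ATPase genes 0 and 1 of 19 were called higher at the 2 ages (medians 0.03 and 0.06; adjusted p = 0.59 and 0.456 with an estimated correlation), and of proteasome core genes 1 and 2 of 18 (medians 0.11 and 0.13; adjusted p = 0.316 and 0.291 with an estimated correlation). Mitochondrial ribosomal protein genes had 0 of 78 called at either age by edgeR (medians 0.05 and 0.03; adjusted p = 0.707 and 0.969 with an estimated correlation). On the log2(TPM + 1) scale the medians at 6 and 11 months turned to -0.09 and -0.06 for V-ATPase and to -0.1 and -0.08 for mitochondrial ribosomal protein genes, and that of proteasome core genes to -0.01 at 6 months. With length and GC offsets mitochondrial ribosomal protein genes had medians of -0.04 and -0.08, with 0 and 3 called lower, and proteasome core genes -0.01 at 6 months; with library size scaling alone the median was -0.02 for V-ATPase genes at 6 months and for mitochondrial ribosomal protein genes at 11 months.

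With age in 5XFAD, cathepsin genes rose in 10 of 13 cases (median 0.79; adjusted p = 0.0364 with an estimated correlation), and their genotype effect differed between the ages with a median interaction of 0.59 (adjusted p = 0.015 with an estimated correlation), with 0 members called by edgeR and 1 with log2(TPM + 1) values. In the same comparison toll-like receptor genes rose in 6 of 10 cases (median 1.17), chemokine genes in 3 of 17 (0.42) and collagen genes in 5 of 43 (0.54), and the calls of these 3 families were lost, with adjusted p = 0.103, 0.169 and 0.243 with an estimated correlation. With length and GC offsets 9 cathepsin, 6 toll-like receptor, 5 chemokine and 2 collagen genes were called higher, and on the log2(TPM + 1) scale the medians of toll-like receptors and collagens were 0.46 and 0.15. The medians of these 4 families stayed above 0 with age in 5XFAD under the scalings tried and with the offsets. V-ATPase genes had 1 higher and 2 lower of 19 (median -0.24; adjusted p = 0.316 with an estimated correlation). In wild type no cathepsin gene was called with age by edgeR (median 0.18; adjusted p = 0.572 with an estimated correlation). In that comparison 1 toll-like receptor, 1 chemokine and 1 collagen gene were called higher and 1 V-ATPase gene lower, with adjusted p from 0.247 to 0.848 with an estimated correlation. Cytosolic ribosomal protein genes had medians of -0.16 in wild type and -0.14 in 5XFAD with age, with 0 and 1 called lower and adjusted p = 0.247 and 0.261 with an estimated correlation, and the medians turned to 0.03 and 0.01 with length and GC offsets.

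Also with age, mitochondrial ribosomal protein genes fell in 12 of 78 cases in wild type (median -0.25) and in 19 of 78 in 5XFAD (median -0.27), and proteasome core genes fell in 8 of 18 and 7 of 18 cases, with 1 higher in 5XFAD. For both families the call was lost, with adjusted p from 0.103 to 0.193 with an estimated correlation, and their medians kept their sign under the scalings tried. With length and GC offsets the medians were -0.17 and -0.20 for mitochondrial ribosomal protein genes, with 2 and 5 called lower, and -0.23 and -0.20 for proteasome core genes, with 0 and 2 called lower. On the log2(TPM + 1) scale 1 and 4 mitochondrial ribosomal protein genes and no proteasome core gene were called lower.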
